A study of Homo sapiens with 18 samples.

How the data were processed

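Primary human epidermal keratinocytes in six-well plates were given PBS, TWEAK, IL-13, IL-22, TWEAK plus IL-13 or TWEAK plus IL-22 for 24 h, with 100 ng/ml of each cytokine and 3 wells per group, per the labels. RNA was taken in TRIzol and sequenced as paired ends on a NovaSeq, and the protocol states that samples failing quality control were eliminated. The deposited table holds whole counts per gene, which the authors' processing notes trace to Bowtie 1.0.0, STAR 2.6.1, HTSeq 0.7.1 and GRCh38. The role of each aligner, the library kit, its strand chemistry, the strand setting of the counting and the annotation release used by the authors are not given in the sources used here. Every column of the table matched a sample by its label, so 18 libraries in 6 groups were used. Gene positions, strands and exons came from GENCODE 29, matched by gene ID. Among tested genes, 3 share a symbol with another. For 6 genes no value is printed, by a rule on sex-linked genes in human samples.

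Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its minimum count of 10, which left 6179 of 58347. Libraries were scaled by TMM factors, and a quasi-likelihood model with 1 mean per group was fitted to all 18 libraries, with 12 residual degrees of freedom and a common biological coefficient of variation of 0.0692. The comparisons were 11 contrasts between 2 groups and 2 interactions, each the pair minus both single treatments plus PBS on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within 1 comparison. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM values are scaled by TMM.

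Gene lists were fixed before the data were examined: 25 of biology and 5 of marker genes for other cell types. The 22 with at least 4 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. The lists cover terminal differentiation, basal keratinocytes, wound keratins, barrier lipids, tight junctions, antimicrobial peptides, CC and CXC chemokines, cytokines and growth factors, STAT6 targets, STAT3 targets, NF-kB, TNF receptors and death signalling, interferon-stimulated genes, antigen presentation, matrix, cell cycle, cholesterol synthesis, the unfolded protein response, hypoxia, immediate early genes, genes raised and lowered in lesional atopic dermatitis skin, ribosomal proteins and mitochondrially encoded genes. Their members came from general knowledge and not from these data. Some lists share members, so their calls are not separate results. SERPINB3 and SERPINB4 are in the lists of STAT6 targets, STAT3 targets and genes raised in lesional skin. CA2 and TNC are in those of STAT6 targets and genes raised in lesional skin. In counts "adjusted over the list alone", the adjustment ran over the members of that list.

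Genes to name were set by a rule written before the data were examined. A gene had to have an adjusted p under 0.05, a mean CPM of at least 2 in the groups compared and a gene symbol other than a clone name, with every library of one group above every library of the other in contrasts of 2 groups. Chance alone gives this order, in either direction, in 1 of 10 splits of 3 against 3. From these came the largest rises and falls (8 each for a single cytokine against PBS, 6 each for a pair against its single cytokine and for interactions, 4 each otherwise), up to 4 members per list with the smallest adjusted p, and a preset set of genes of interest. Some genes that the rule names are not reported here. The text names a selection of the others, mostly those that kept their call in every alternative fixed in advance. Genes of the strand pairs, MT-RNR2, the CPM values of genes in the figure of levels and the genes credited with counts of another gene were chosen after their values were seen.

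Alternatives fixed in advance were RLE factors, total counts as scaling, no filter on low counts, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, a model with a block per replicate number, a model of only the groups compared, each library left out in turn, camera with an estimated correlation, and fry. Random splits of the libraries of the groups compared were fitted the same way, all 10 splits of 3 against 3 and 100 random splits otherwise. An added analysis credited the counts of each gene with an opposite exon to the overlapping gene on the other strand, and this was chosen after the data were seen. Overlap of changes against shared PBS wells was set against 50 simulations of unchanged groups. The model was tested on simulated data with 200 of 6179 genes changed. For TWEAK against PBS it found 29.9, 62.7 and 90.9% of 1.5-, 2- and 4-fold changes, and 6.15% of 130 calls were unchanged genes, above the nominal 5%. For the interaction with IL-13 it found 14.9, 46.3 and 71.2%, and 2.22% of 90 calls were unchanged. A list shifted in simulation was called, with 1 other of the 22.

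Total counts were 39724 in PBS replicate 1 and 628425 to 989902 in the other libraries. At these depths and with 3 wells per group, most simulated 1.5-fold changes were missed. No pair of libraries was a duplicate. Raw reads were not analysed here, so neither strand nor alignment was tested at the level of reads. No library was left out of the results reported.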

Results

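RNA was sequenced from primary human epidermal keratinocytes, the cells that form the outer layer of the skin, after 24 h in culture with PBS, TWEAK, IL-13, IL-22, TWEAK plus IL-13 or TWEAK plus IL-22. TWEAK, encoded by TNFSF12, is a cytokine of the TNF family whose receptor is encoded by TNFRSF12A. IL-13 is a type 2 cytokine that acts through STAT6, and IL-22 is a lymphocyte cytokine that acts on epithelia through STAT3. Each cytokine was used at 100 ng/ml. Every one of the 6 groups held 3 wells, which gave 18 libraries. The series title places TWEAK beside genes related to atopic dermatitis, an inflammatory skin disease in which IL-13 and IL-22 are both active. The labels do not say that the wells came from separate cultures or donors, so p-values measure the spread between these wells, which may be technical.

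The deposited table gave whole counts for 58347 genes, of which 6179 passed the filter on low counts. Total counts ran from 628425 to 989902 in 17 libraries, with a median over all 18 of 830378.5. PBS replicate 1 held 39724 counts over 6103 genes, and its correlation across genes with the other PBS libraries was 0.751 to 0.774, against 0.957 to 0.976 for the other pairs of wells from 1 group. It also held 0.3% of its counts in MT-RNR2, the mitochondrial large ribosomal RNA (exact 95% binomial interval 0.248 to 0.358%), against 0.0181 to 0.0478% in the other 17 libraries. This library was kept in every comparison, and counts of called genes without it stand beside those with PBS.

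Most counts lay in genes that overlap an abundant messenger on the other strand. Genes whose exons overlap an exon of a gene on the opposite strand held 90.7% of all 14312948 counts, and antisense RNA genes alone held 48.7%. AC006064.4, opposite the glycolytic gene GAPDH, held 481397 counts against 787 for GAPDH itself, and BEST1, opposite the ferritin gene FTH1, held 206007 against 528. KRT8, opposite its keratin partner KRT18, held 60209 counts against 665. The 35 ribosomal protein genes of a fixed list held 0.198% of all counts. In the mitochondrial genome, MT-ND6, the single messenger of the light strand, held 268400 counts per kb, against a median of 9048 for the 12 heavy-strand messengers. Neither the kit's strand chemistry nor the strand setting of the counting is given in the sources used here, so the counts of a gene written below as "X (opposite Y)" cannot be assigned to X or to Y with certainty. Of the 6179 genes tested, 1596 had no opposite exon. The strand of their counts is not known either, so lack of an opposite exon does not assign counts to the gene named with certainty. The 13 mitochondrially encoded genes of a fixed list, 0 of them with an opposite exon, share this limit wherever they are named as risen or fallen.

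**Figure D1:**
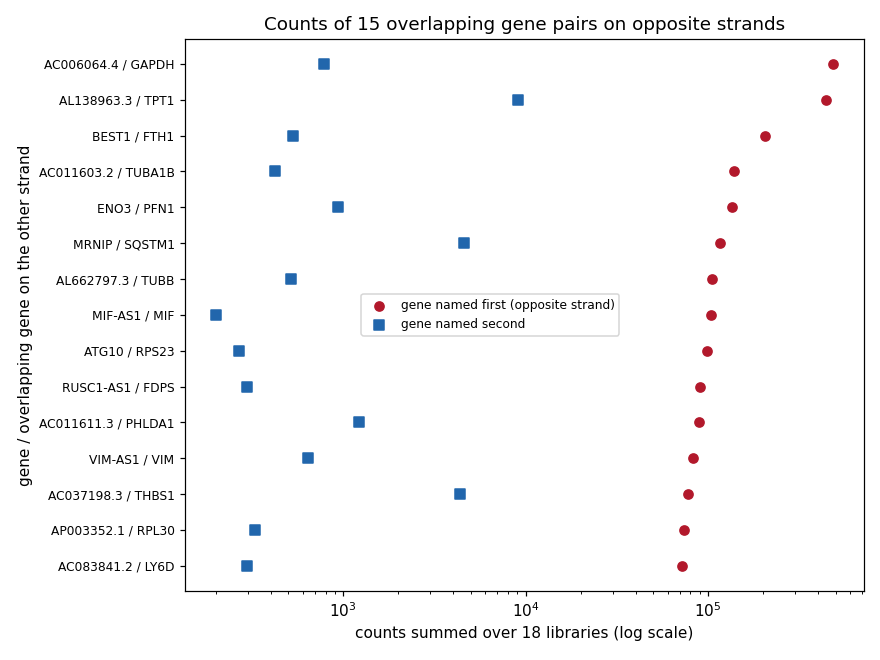
Counts summed over 18 libraries (x axis, log scale) for pairs of genes whose exons overlap on opposite strands (y axis). Red circles are the gene named first and blue squares the gene named second. AC006064.4 held 481397 counts and GAPDH 787. Pairs were chosen for the highest counts of the gene named first, so that it held more in every pair drawn follows from the choice.

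Changes are given below as fold or as log2 fold change ± standard error from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 3 wells per group. Positions are on GRCh38. Credited counts are those of each gene with an opposite exon given to the overlapping gene on the other strand, an alternative chosen after the data were seen. Each gene named as risen or fallen between 2 groups in the counts as deposited had all wells of one group above all wells of the other. No such condition was set for members counted in lists or for genes in credited counts. Ratios carry 95% counting intervals only where a group held some counts but at most 3. These intervals and the floors behind "at least" cover counting error only. Other ratios on few counts carry no interval. TMEM99 (opposite KRT10) held 3, 4 and 1 counts with TWEAK plus IL-13 and 2, 0 and 2 with TWEAK plus IL-22. CA2 held 6 counts with TWEAK.

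TWEAK alone against PBS showed what the cytokine did by itself. SLC12A5-AS1 (opposite MMP9), on chromosome 20 from 46013500 to 46022073, rose 33.9-fold (log2 5.08 ± 0.14), from 230 ± 6.24 to 7840 ± 591 CPM (mean ± SD). MMP9, the gelatinase that degrades type IV collagen, lies at 46008908 to 46016561 on the other strand and held 64 counts with TWEAK against 1 with PBS, a ratio of 35.7 (interval 6.18 to 1430). APOBEC3B-AS1 (opposite the cytidine deaminase gene APOBEC3B) rose 7.71-fold, and PLA2G4C-AS1 (opposite the phospholipase gene PLA2G4C) held 61 counts against 0, at least 11.3-fold higher by a floor of 3 counts over the group. H19_1 (opposite the imprinted RNA gene H19), a 71-base RNA annotated on chromosome 11 from 1996540 to 1996610, fell to 0.241 of its PBS level (log2 -2.05 ± 0.10).

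CRYM-AS1 (log2 -2.74 ± 0.48), FLNC-AS1 (opposite the actin crosslinker gene FLNC, -1.67 ± 0.26), PDCD4-AS1 (-1.38 ± 0.24) and the matricellular gene CYR61 (-1.57 ± 0.33) also fell. HSPA5, the main chaperone of the endoplasmic reticulum, rose by 1.15 ± 0.27, a call lost without TWEAK replicate 1 (0.92), and B3GALT6, a galactosyltransferase of proteoglycan synthesis, by 2.17 ± 0.46, lost without PBS replicate 3 (1.92). The integrin gene ITGAV (opposite AC017101.1) rose by 0.98 ± 0.24; this call was lost without PBS replicate 2 (0.92), without TWEAK replicate 1 (0.82) and when only the groups compared were fitted (0.99). GDNF-AS1 (opposite the growth factor gene GDNF) fell by 1.52 on the log2 scale, lost without PBS replicate 3 (-1.46). NFKBIA, the inhibitor that NF-kB itself induces, rose by 0.78 ± 0.24, a call lost without PBS replicate 2 (0.75), PBS replicate 3 (0.88) or TWEAK replicate 3 (0.61), with DESeq2 (0.77), with total counts (0.74), with either other filter (0.84 and 0.81) and with only the groups compared (0.78). TNFRSF12A (opposite CLDN6), the TWEAK receptor, did not pass the test (log2 -0.61 ± 0.29).

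Among the lists fixed before the data were examined, that of 13 mitochondrially encoded genes was the one called after TWEAK (camera adjusted p = 9.3e-07; adjusted p = 0.615 with an estimated correlation). Of these, 4 rose and 9 rose when adjusted over the list alone. None has credited counts, so a rise in their counts may not be a rise of the messengers named. PBS replicate 1, the library with the high MT-RNR2 share, is among the PBS wells. The calls of MT-ATP6 and MT-CO1 given next were kept without that library. The list was also called with TWEAK against IL-13 and with TWEAK plus IL-13 against IL-13, where no PBS well was compared. MT-ATP6 rose by 0.56 ± 0.14 and MT-CO1 by 0.44 ± 0.12; both calls were lost with DESeq2 (0.73 and 0.50) and without PBS replicate 2 (0.37 and 0.26), and that of MT-CO1 also with only the groups compared (0.47) and without TWEAK replicate 1 (0.42) or 3 (0.41). Of 14 measured genes raised in lesional atopic dermatitis skin, 0 passed in edgeR or DESeq2, and 0 reached an unadjusted p under 0.05 (camera adjusted p = 0.94, direction lower, though their median log2 change was 0.04 and their mean 0.19). In credited counts the direction was higher, with 2 of 4 risen (adjusted p = 0.0229 with an estimated correlation). Of 17 matrix genes, 4 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.186), and of 11 NF-kB genes 1 rose and 1 fell, 2 and 1 adjusted over the list alone (adjusted p = 0.446). Of 9 interferon-stimulated genes 0 passed in edgeR or DESeq2, 2 rose adjusted over the list alone, and 4 higher and 1 lower reached an unadjusted p under 0.05 (adjusted p = 0.0588). These 3 lists were called as higher in credited counts (each adjusted p = 0.0205 with an estimated correlation). The test called 296 genes, 185 higher and 111 lower, 93 of them by at least 2-fold, and 367 without PBS replicate 1. The count was 147 with only the groups compared, 193 with the CPM filter and 197 with no filter. Among the 39 called genes with no opposite exon, 22 were higher and 17 lower. With total counts as the scaling, the higher share of the calls went from 62.5 to 49.2%.

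IL-13 against PBS gave the type 2 response of these cells. SERPINB11 (opposite SERPINB3), on chromosome 18 from 63647579 to 63726432, rose 15.9-fold (log2 3.99 ± 0.11), from 435 ± 89.7 to 7590 ± 694 CPM. SERPINB4 (3.68 ± 0.49) and SERPINB3 (opposite SERPINB11, 3.34 ± 0.31), the squamous cell carcinoma antigens, rose with it; they are near-identical paralogs, so reads could be split between them. CA2, a carbonic anhydrase, held 80 counts against 2, a ratio of 21.5 (interval 5.77 to 181). TNC (opposite DEC1), the matrix protein tenascin C, rose 4.32-fold (2.11 ± 0.22). CYP1B1-AS1 (opposite the cytochrome P450 gene CYP1B1) rose 10.2-fold and ANO1-AS1 (opposite the chloride channel gene ANO1) 10.3-fold.

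DSG1 (opposite DSG1-AS1), a desmosomal cadherin of upper epidermal layers, rose by 1.93 ± 0.29, THBS1 (opposite FSIP1), a matricellular protein, by 1.47 ± 0.17, and the wound keratin KRT6A, whose paralogs KRT6B and KRT6C are near-identical, by 0.61 ± 0.13. DSG1-AS1 (opposite DSG1) changed less than DSG1, from 418 ± 33.7 CPM with PBS to 557 ± 57.5 with IL-13. WTAPP1 (opposite the collagenase gene MMP1) fell by 2.17 on the log2 scale, PSORS1C1 (opposite the corneodesmosin gene CDSN) by 1.64, SLC12A5-AS1 (opposite MMP9) by 1.60 and the transcription factor gene ELK3 (opposite AC008149.1) by 1.62. TIMP1, an inhibitor of matrix proteases, fell by 1.28 on the log2 scale and the interferon-stimulated IFI6 by 1.19; both calls were lost without PBS replicate 3 (-0.70 and -0.98).

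Of 8 measured STAT6 targets, 4 rose with IL-13, 4 adjusted over the list alone (camera adjusted p = 0.000103; adjusted p = 0.0241 with an estimated correlation). Among genes raised in lesional atopic dermatitis skin, 7 of 14 rose and 2 fell, likewise adjusted over the list alone (adjusted p = 0.00164, and 0.383 with an estimated correlation). In credited counts the direction turned to lower and the call ended, with 1 risen and 1 fallen of 4 (adjusted p = 0.895, and 0.94 with an estimated correlation). Matrix genes were lower as a set (adjusted p = 0.00285; 0.383 with an estimated correlation), with 6 of 17 fallen and 2 risen, 7 and 2 adjusted over the list alone; the set call was lost without PBS replicate 3 (adjusted p = 0.0644). Basal keratinocyte genes were lower, 6 of 17 fallen and 8 adjusted over the list alone (adjusted p = 0.00798; 0.716 with an estimated correlation; 0.964 without PBS replicate 3). Ribosomal protein genes were lower, 3 of 30 fallen and 5 adjusted over the list alone (adjusted p = 0.00756; 0.716 with an estimated correlation; 0.474 without PBS replicate 3). Interferon-stimulated genes were lower, 2 of 9 fallen and 2 adjusted over the list alone (adjusted p = 0.0265; 0.258 with an estimated correlation), a call lost without PBS replicate 1 (adjusted p = 0.0787), PBS replicate 3 (0.125) or IL-13 replicate 2 (0.122). In credited counts the calls of matrix (adjusted p = 0.0538), ribosomal (0.945) and interferon-stimulated genes (0.843) ended. The test called 391 genes, 188 higher and 203 lower, 141 by at least 2-fold; the count was 472 without PBS replicate 1 and 259 without PBS replicate 3. The balance turned without PBS replicate 2 (186 higher, 166 lower), PBS replicate 3 (134, 125) or IL-13 replicate 1 (163, 143), with no filter (177, 89) and with the CPM filter (155, 123). Among the 69 called genes with no opposite exon, 19 were higher and 50 lower.

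IL-22 against PBS raised some of the same genes and lowered others. SERPINB11 (opposite SERPINB3) rose 7.1-fold (log2 2.83 ± 0.11), SERPINB4 8.92-fold (3.16 ± 0.53) and SERPINB3 7.23-fold (2.85 ± 0.33). TMEM99 (opposite KRT10, the keratin of differentiating suprabasal cells), on chromosome 17 from 40819106 to 40836274, fell to 0.141 of its PBS level (-2.83 ± 0.23), from 136 ± 28.6 to 20.2 ± 10.1 CPM. DSCAS (opposite DSC1, a desmosomal cadherin of upper layers), on chromosome 18 from 31101588 to 31162789, fell by 2.03 on the log2 scale. S100A8, an alarmin, held 29 counts against 1, a ratio of 15.5 (interval 2.57 to 634), a call lost without PBS replicate 2 or 3 or IL-22 replicate 1 or 3, with fitted log2 values of 2.99, 6.12, 3.59 and 3.49.

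MMP1 (opposite WTAPP1) rose by 1.34 ± 0.26, KRT6A by 0.65 ± 0.13, the glycolytic enzyme gene ENO1 (opposite ENO1-AS1) by 1.01 ± 0.20, CYP1B1-AS1 (opposite CYP1B1) by 1.96 ± 0.16 and C5orf56 (opposite the transcription factor gene IRF1) by 1.91 ± 0.32. DSG3, a desmosomal cadherin of lower layers, rose by 1.14 ± 0.23 and THBS1 (opposite FSIP1) by 0.86 ± 0.18, both lost without PBS replicate 2 (0.87 and 0.57). CYR61 fell by 1.67 on the log2 scale, SBF2 (opposite SBF2-AS1) by 1.51, SPIN4-AS1 (opposite SPIN4) by 1.22 and the transcription factor gene FOXQ1 by 1.66, the last lost without PBS replicate 2 (-1.41).

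Genes raised in lesional atopic dermatitis skin were higher after IL-22, 7 of 14 risen and 1 fallen, 9 and 1 adjusted over the list alone (camera adjusted p = 4.92e-09; adjusted p = 0.0912 with an estimated correlation), and 3 of 4 rose in credited counts (adjusted p = 5.24e-05 with an estimated correlation). STAT3 targets rose in 4 of 7, 4 adjusted over the list alone (camera adjusted p = 0.000889, and 0.0912 with an estimated correlation). STAT6 targets rose in 3 of 8, 4 adjusted over the list alone (camera adjusted p = 0.00573, 0.0912 with an estimated correlation, 0.0678 without PBS replicate 2). SERPINB3 and SERPINB4, both risen, belong to these lists and to that of lesional skin. The 3 calls are therefore not separate results, and that of STAT6 targets does not by itself show STAT6 activity. Mitochondrially encoded genes rose in 5 of 13, 11 adjusted over the list alone (adjusted p = 1.03e-08; 0.226 with an estimated correlation); the PBS wells again include the library with the high MT-RNR2 share. The wound and stress keratins (1 of 9 risen, 2 adjusted over the list alone) had an adjusted p of 0.0261, 0.503 with an estimated correlation, and lost the call without PBS replicate 1 (adjusted p = 0.0583) or 2 (0.267). Basal genes had an adjusted p of 0.00914, 0.61 with an estimated correlation, and lost the call without PBS replicate 1 (adjusted p = 0.0634) or 2 (0.708). Among those 17 basal genes edgeR and DESeq2 called 0, and 5 higher reached an unadjusted p under 0.05. The test called 240 genes, 97 higher and 143 lower; the count was 308 without PBS replicate 1, 120 without PBS replicate 2, 143 without IL-22 replicate 1, 133 with the CPM filter and 155 with only the groups compared. With no filter 63 were higher and 61 lower, and among the 31 called genes with no opposite exon 18 were higher and 13 lower.

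**Figure D2:**
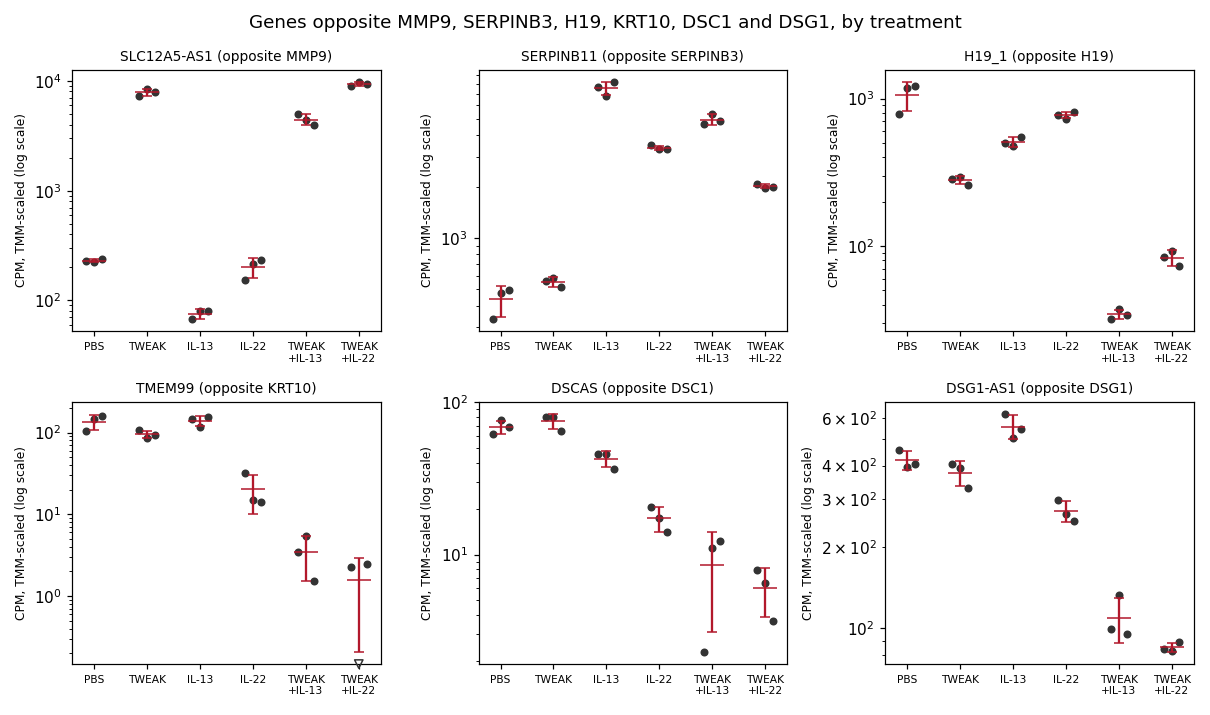
CPM scaled by TMM (y axes, log scale) of 6 genes by treatment (x axes). Black points are wells, red bars the mean ± SD of 3 wells and an open triangle on the axis a well with 0 counts; SLC12A5-AS1 averaged 7840 CPM with TWEAK against 230 with PBS, and TMEM99 3.49 with TWEAK plus IL-13 against 136 with PBS.

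TWEAK plus IL-13 against PBS gave the change with both cytokines, which for some genes was not the sum of the single changes. Among genes opposite differentiation genes, TMEM99 (opposite KRT10) fell to 0.0248 of its PBS level (log2 -5.33 ± 0.34) and DSCAS (opposite DSC1) to 0.114 (-3.14 ± 0.34). H19_1 (opposite H19) fell to 0.0296 of its PBS level (-5.08 ± 0.14), and CXCL14 (opposite AC034206.1), a chemokine made constitutively by epidermis, to 0.0468 (-4.42 ± 0.34). TNC (opposite DEC1) rose 7.58-fold (2.92 ± 0.20), THBS1 (opposite FSIP1) 5.02-fold (2.33 ± 0.16) and ITGAV (opposite AC017101.1) 4.18-fold (2.06 ± 0.22). HSPA5 rose 4.12-fold (2.04 ± 0.25) and NFKBIA 3.38-fold (1.75 ± 0.22).

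SERPINB4 rose by 3.83 ± 0.49, SERPINB3 (opposite SERPINB11) by 3.32 ± 0.31, NFKB2, a subunit of non-canonical NF-kB, by 1.98 ± 0.48, B2M, the light chain of class I MHC, by 1.46 ± 0.29, the cytokine gene IL1A by 1.26 ± 0.26 and P-cadherin, CDH3 (opposite AC126773.2), by 1.25 ± 0.27. OR2I1P (opposite UBD, the ubiquitin-like FAT10 gene) held 67 counts against 1, a ratio of 41 (interval 7.11 to 1640), and PLA2G4C-AS1 (opposite PLA2G4C) 56 against 0, at least 11.4-fold higher. The glucose transporter gene SLC2A1 (opposite SLC2A1-AS1) fell by 1.60 on the log2 scale and the EGF receptor ligand EREG by 1.03. The lists called were STAT6 targets, 4 of 8 risen and 1 fallen, the same adjusted over the list alone (adjusted p = 0.00242; 0.145 with an estimated correlation), the unfolded protein response, 5 of 11 risen and 6 adjusted over the list alone (adjusted p = 0.00169; 0.206 with an estimated correlation), and mitochondrially encoded genes, 6 of 13 risen and 9 adjusted over the list alone (adjusted p = 0.0013; 0.635 with an estimated correlation). The PBS wells here too include the library with the high MT-RNR2 share. Genes raised in lesional skin counted 5 of 14 risen and 1 fallen, 5 and 2 adjusted over the list alone (adjusted p = 0.0628), and 1 risen and 1 fallen of 4 in credited counts (adjusted p = 0.182, and 0.262 with an estimated correlation). The test called 1028 genes, 493 higher and 535 lower (529 and 505 with RLE factors, 388 and 333 with no filter, 370 and 351 with DESeq2, 375 and 359 without PBS replicate 2), and 1103 without PBS replicate 1. Among the 173 called genes with no opposite exon the balance turned, with 95 higher and 78 lower.

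TWEAK plus IL-22 against PBS kept the MMP9 locus high and the KRT10 locus low. SLC12A5-AS1 (opposite MMP9) rose 40.5-fold (log2 5.34 ± 0.14) and MMP9 held 74 counts against 1, a ratio of 41.1 (interval 7.16 to 1650). TMEM99 (opposite KRT10) fell to 0.0119 of its PBS level (-6.40 ± 0.38), DSCAS (opposite DSC1) to 0.0863 and H19_1 (opposite H19) to 0.0718. TMEM99 held 2, 0 and 2 counts in the wells with both cytokines, so the size of its fall is imprecise. LAMA3, a laminin gene of the basement membrane with no opposite exon, rose 2.1-fold (1.07 ± 0.15). AREG, an EGF receptor ligand, fell by 1.59 on the log2 scale and SPRR1B, a cornified envelope precursor, by 2.29.

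ITGAV (opposite AC017101.1) rose by 1.22 ± 0.24, HSPA5 by 1.33 ± 0.27, B2M by 1.17 ± 0.30, HSP90B1, a second chaperone of the endoplasmic reticulum (opposite C12orf73), by 0.84 ± 0.17, SERPINB4 by 2.24 ± 0.60 and the mitochondrial superoxide dismutase gene SOD2 (opposite WTAP) by 0.54 ± 0.10. PARP9 (opposite DTX3L), an interferon-stimulated gene, rose by 0.91 ± 0.21, a call lost without PBS replicate 3 (0.71). The list called was that of mitochondrially encoded genes, 7 of 13 risen and 10 adjusted over the list alone (adjusted p = 0.00011; 0.571 with an estimated correlation), and the PBS wells include the library with the high MT-RNR2 share. Interferon-stimulated genes counted 4 of 9 risen, 7 risen and 2 fallen adjusted over the list alone (adjusted p = 0.0754), and genes raised in lesional skin 5 of 14 risen and 1 fallen, the same adjusted over the list alone (adjusted p = 0.279). In credited counts both lists were called, with 4 of 5 and 4 of 4 risen (adjusted p = 0.00639 and 0.000702 with an estimated correlation). The test called 984 genes, 487 higher and 497 lower (508 and 479 with RLE factors, 426 and 277 with no filter, 353 and 337 with DESeq2, 393 and 374 without PBS replicate 2, 407 and 406 without TWEAK plus IL-22 replicate 1), and 1087 without PBS replicate 1. Among the 155 called genes with no opposite exon, 67 were higher and 88 lower.

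TWEAK plus IL-13 against IL-13 asked what TWEAK added to cells given IL-13. SLC12A5-AS1 (opposite MMP9) rose 58.1-fold (log2 5.86 ± 0.14), from 76 ± 7.6 to 4440 ± 504 CPM, and MMP9 held 52 counts against 0, at least 19.7-fold higher. LAMA3 rose 3.23-fold (1.69 ± 0.15) and ITGB4, the integrin subunit of hemidesmosomes, 1.81-fold (0.86 ± 0.18). TMEM99 (opposite KRT10) fell to 0.0265 of its level with IL-13 (-5.24 ± 0.32), DSG1 (opposite DSG1-AS1) to 0.252 (-1.99 ± 0.25) and the wound keratin KRT16 to 0.498. MYH3, an embryonic myosin heavy chain gene with no opposite exon, rose 12.2-fold (3.61 ± 0.22), and the simple epithelial keratin gene KRT7 (opposite KRT7-AS) 5.94-fold (2.57 ± 0.44).

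NFKBIA rose by 1.73 ± 0.18, NFKB2 by 2.41 ± 0.42, IL1A by 1.27 ± 0.22, B2M by 1.09 ± 0.23, HSPA5 by 2.11 ± 0.21, HSP90B1 (opposite C12orf73) by 1.40 ± 0.14, ITGAV (opposite AC017101.1) by 1.59 ± 0.17 and the caspase inhibitor gene CFLAR (opposite IMPDH1P10) by 1.26 ± 0.31. OR2I1P (opposite UBD) held 67 counts against 0, at least 25.4-fold higher, and G0S2, an inhibitor of lipolysis, 28 against 1, a ratio of 31.8 (interval 5.26 to 1300). CXCL14 (opposite AC034206.1, log2 -2.45 ± 0.41), H19_1 (opposite H19, -3.88 ± 0.15), the small heat shock gene CRYAB (opposite HSPB2, -2.93 ± 0.42), CA3-AS1 (opposite CA3, -2.89 ± 0.41), PTGS2, the inducible cyclooxygenase (-1.66 ± 0.25), and SLC2A1 (opposite SLC2A1-AS1, -1.23 ± 0.22) fell. The alarmin IL33 held 2 counts against 24 with IL-13 alone, a ratio of 10.6 (interval 2.62 to 92.2), a call lost without IL-13 replicate 3 or TWEAK plus IL-13 replicate 1 (fitted log2 -2.70 and -2.57).

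Matrix genes rose as a set when TWEAK was added to IL-13, 9 of 17 risen and 9 adjusted over the list alone (adjusted p = 1.25e-06; 0.114 with an estimated correlation). So did the unfolded protein response, 5 of 11 and 7 adjusted over the list alone (adjusted p = 1.54e-05; 0.0914 with an estimated correlation). Mitochondrially encoded genes rose in 5 of 13, 6 adjusted over the list alone (adjusted p = 0.00784; 0.603 with an estimated correlation; 0.0601 without IL-13 replicate 2). NF-kB genes counted 4 of 11 risen and 1 fallen, 5 and 1 adjusted over the list alone (adjusted p = 0.0348; 0.179 with an estimated correlation), a call lost without IL-13 replicate 1 (adjusted p = 0.0616) or 2 (0.077) and with total counts (0.0558). Cholesterol synthesis genes rose in 3 of 14, 3 adjusted over the list alone (adjusted p = 0.0348; 0.46 with an estimated correlation), lost without IL-13 replicate 1 (adjusted p = 0.0616), IL-13 replicate 2 (0.0779) or TWEAK plus IL-13 replicate 3 (0.0679) and with total counts (0.0563). The direction of that list turned to lower and the call ended in credited counts, with 1 risen and 1 fallen of 7 (adjusted p = 0.882). Of genes raised in lesional skin, 4 rose and 4 fell of 14, 5 and 4 adjusted over the list alone (adjusted p = 0.993), and 2 rose and 1 fell of 4 in credited counts (adjusted p = 0.198 with an estimated correlation). The test called 1063 genes, 515 higher and 548 lower, 352 by at least 2-fold; DESeq2 called 679. The balance turned with RLE factors, to 605 higher and 471 lower, and with DESeq2, to 374 and 305, and among the 209 called genes with no opposite exon 148 were higher and 61 lower.

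TWEAK plus IL-22 against IL-22 gave the matching comparison. SLC12A5-AS1 (opposite MMP9) rose 47-fold (log2 5.56 ± 0.12) and MMP9 held 74 counts against 1, a ratio of 76.9 (interval 13.4 to 3080). LAMA3 rose 1.89-fold (0.92 ± 0.13) and MYH3 7.96-fold (2.99 ± 0.24). PTGS2 fell to 0.172 of its level with IL-22 (-2.54 ± 0.22), CXCL14 (opposite AC034206.1) to 0.231, KRT16 to 0.527 and KRT6A to 0.631. The near-identical KRT6C fell to 0.132 (-2.92 ± 0.53).

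DSG1 (opposite DSG1-AS1) fell by 1.58 on the log2 scale, DSG3 by 0.88, AREG by 0.91, SERPINB13, a serpin of stratified epithelium, by 1.31, PPP1R15A, a phosphatase subunit of the integrated stress response, by 1.34, TMEM99 (opposite KRT10) by 3.57 and H19_1 (opposite H19) by 3.21. G0S2 held 55 counts against 3, a ratio of 19 (interval 6.19 to 95.2), and SSPN (opposite AC022509.1), a membrane protein of the dystrophin complex, rose by 3.13 ± 0.60. NFKBIA rose by 0.78 ± 0.20, lost without IL-22 replicate 2 (0.63), and HSPA5 by 0.76 ± 0.20, lost with DESeq2 (0.76) and without TWEAK plus IL-22 replicate 1 (0.66). The basal keratins KRT14 and KRT5 fell by 0.54 and 0.56 on the log2 scale, both lost with DESeq2 (-0.54 and -0.56).

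Genes raised in lesional atopic dermatitis skin were lower when TWEAK was added to IL-22, 6 of 14 fallen, 8 fallen and 1 risen adjusted over the list alone (adjusted p = 0.000589; 0.428 with an estimated correlation). This call ended in credited counts, with 1 risen and 1 fallen of 4 (adjusted p = 0.733, and 0.787 with an estimated correlation). STAT3 targets fell in 3 of 7, 3 adjusted over the list alone, hypoxia and glycolysis genes in 3 of 16, 4 adjusted over the list alone, and interferon-stimulated genes rose in 3 of 9, 4 adjusted over the list alone; each had an adjusted p of 0.0475, 0.428 with an estimated correlation, and each call was lost with total counts (adjusted p = 0.11). The STAT3 call also ended in credited counts (adjusted p = 0.165). The STAT3 call was lost without IL-22 replicate 1 (adjusted p = 0.125) or 3 (0.0625) or TWEAK plus IL-22 replicate 2 (0.103) or 3 (0.129). The hypoxia call was lost without IL-22 replicate 1 (adjusted p = 0.209) or TWEAK plus IL-22 replicate 2 (0.103) or 3 (0.0843). The interferon call was lost without IL-22 replicate 1 (adjusted p = 0.0759), 2 (0.08) or 3 (0.0625) or TWEAK plus IL-22 replicate 1 (0.111) or 3 (0.0843). The test called 640 genes, 330 higher and 310 lower, 401 with DESeq2, 387 with no filter and 405 with the CPM filter, and the balance turned with total counts, to 305 higher and 411 lower, and without IL-22 replicate 1, to 242 and 249. Among the 119 called genes with no opposite exon, 38 were higher and 81 lower.

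TWEAK plus IL-13 against TWEAK showed what IL-13 added. SERPINB4 rose 15.8-fold (log2 3.99 ± 0.41), SERPINB3 (opposite SERPINB11) 10.8-fold (3.43 ± 0.26), CA2 13.6-fold (3.77 ± 0.49), TNC (opposite DEC1) 6.68-fold (2.74 ± 0.16) and THBS1 (opposite FSIP1) 2.94-fold (1.56 ± 0.13). IDI1 (opposite IDI2-AS1) and HMGCS1 (opposite AC114947.2), enzymes of the cholesterol pathway, rose 1.94-fold and 2.01-fold. TMEM99 (opposite KRT10) fell to 0.0388 of its level with TWEAK (-4.69 ± 0.34), DSCAS (opposite DSC1) to 0.109 and H19_1 (opposite H19) to 0.123. FN1, fibronectin, fell to 0.422 (-1.25 ± 0.16) and PTGS2 to 0.364.

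OR2I1P (opposite UBD) held 67 counts against 3 with TWEAK, a ratio of 24.5 (interval 8.03 to 122). HSPA5 rose by 0.90 ± 0.18, NFKBIA by 0.97 ± 0.17, B2M by 0.98 ± 0.23, PHGDH, the first enzyme of serine synthesis, by 1.45 ± 0.35 and the BH3-only gene PMAIP1 by 1.02 ± 0.24. STAT6 targets rose in 4 of 8, 6 risen and 1 fallen adjusted over the list alone (adjusted p = 1.68e-06; 0.00792 with an estimated correlation). The other lists called were the unfolded protein response, 3 of 11 risen and 4 adjusted over the list alone (adjusted p = 0.000479; 0.117 with an estimated correlation), and cholesterol synthesis, 5 of 14 risen and 7 adjusted over the list alone (adjusted p = 0.000764; 0.279 with an estimated correlation; 0.172 in credited counts). Lesional-skin genes counted 5 risen and 2 fallen of 14, 5 and 3 adjusted over the list alone (adjusted p = 0.0105; 0.397 with an estimated correlation; 0.0514 without TWEAK replicate 3). In credited counts their direction turned to lower and the call ended, with 1 risen and 2 fallen of 4 (adjusted p = 0.746, and 0.755 with an estimated correlation). Interferon-stimulated genes counted 3 fallen of 9, 1 risen and 4 fallen adjusted over the list alone (adjusted p = 0.0421; 0.201 with an estimated correlation), lost without TWEAK replicate 3 (adjusted p = 0.0743) or TWEAK plus IL-13 replicate 1 (0.129) or 3 (0.0564) and with total counts (0.0532). The test called 515 genes, 210 higher and 305 lower, and 337 with DESeq2; with RLE factors 264 were higher and 261 lower, a higher share of 50.3% against 40.8%. Among the 93 called genes with no opposite exon, 57 were higher and 36 lower.

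TWEAK plus IL-22 against TWEAK moved fewer genes. SERPINB11 (opposite SERPINB3) rose 3.65-fold (log2 1.87 ± 0.10), SERPINB4 5.26-fold (2.40 ± 0.50), MMP1 (opposite WTAPP1) 2-fold and PDPN, the membrane glycoprotein podoplanin, 3.14-fold (1.65 ± 0.38). TMEM99 (opposite KRT10) fell to 0.0186 of its level with TWEAK (-5.75 ± 0.38), DSCAS (opposite DSC1) to 0.083, SPRR1B to 0.223, PTGS2 to 0.384 and AREG to 0.59. The TMEM99 ratio rests on 2, 0 and 2 counts with both cytokines. NDRG1, a gene induced in hypoxia and differentiation, rose by 0.91 ± 0.17 and PARP9 (opposite DTX3L) by 0.78 ± 0.17. STAT6 targets (2 of 8 risen, 4 adjusted over the list alone; adjusted p = 0.0171, 0.293 with an estimated correlation) and STAT3 targets (3 of 7 risen, 4 risen and 1 fallen adjusted over the list alone; adjusted p = 0.0171, 0.309 with an estimated correlation, 0.0947 without TWEAK plus IL-22 replicate 1) were called. Basal genes (1 of 17 risen, 2 adjusted over the list alone; adjusted p = 0.0234, 0.764 with an estimated correlation) lost the call without TWEAK replicate 2 (adjusted p = 0.761) or TWEAK plus IL-22 replicate 1 (0.0691). The test called 240 genes, 74 higher and 166 lower, a higher share of 30.8% that became 42.4% with total counts and 40.8% with RLE factors. It called 158 without TWEAK plus IL-22 replicate 2, 119 with no filter and 129 with the CPM filter. Among the 29 called genes with no opposite exon, 11 were higher and 18 lower. Genes raised in lesional skin were called in credited counts alone, with 3 of 4 risen (adjusted p = 0.000237 with an estimated correlation).

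TWEAK against IL-13 set both single treatments side by side. SLC12A5-AS1 (opposite MMP9) was higher with TWEAK by 6.68 ± 0.14 on the log2 scale, FN1 4.11-fold (2.04 ± 0.17), LAMA3 3.36-fold (1.75 ± 0.15) and MMP1 (opposite WTAPP1) 5.78-fold (2.53 ± 0.36). SERPINB11 (opposite SERPINB3) was lower with TWEAK, at 0.0727 of its IL-13 level (-3.78 ± 0.10), as were CA2 (0.0827), TNC (opposite DEC1, 0.263), DSG1 (opposite DSG1-AS1, 0.25) and KRT16 (0.488). DSG1-AS1 (opposite DSG1) differed less than DSG1, at 376 ± 40 CPM with TWEAK and 557 ± 57.5 with IL-13. The interferon-stimulated genes IFI44L and HERC6 were 8.24-fold (3.04 ± 0.58) and 4.87-fold (2.29 ± 0.50) higher with TWEAK. As a set, interferon-stimulated genes were higher with TWEAK, 4 of 9 and 6 adjusted over the list alone (adjusted p = 3.46e-05; 0.00966 with an estimated correlation), and STAT6 targets lower, 4 of 8 and 4 adjusted over the list alone (adjusted p = 6.89e-06; 0.00966 with an estimated correlation).

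Matrix genes counted 9 higher and 2 lower of 17, 11 and 2 adjusted over the list alone (adjusted p = 1.89e-05; 0.141 with an estimated correlation), and genes raised in lesional skin 3 higher and 7 lower of 14, 3 and 8 adjusted over the list alone (adjusted p = 0.000759; 0.297 with an estimated correlation). The last list turned to higher and lost the call in credited counts, with 3 higher and 1 lower of 4 (adjusted p = 0.127, and 0.199 with an estimated correlation). Mitochondrially encoded genes were higher in 5 of 13, 6 adjusted over the list alone (adjusted p = 0.00149; 0.388 with an estimated correlation). Basal genes, 4 of 17 higher and 5 adjusted over the list alone (adjusted p = 0.0013; 0.388 with an estimated correlation), lost the call without TWEAK replicate 1 (adjusted p = 0.0687). Wound keratins, 1 of 9 higher and 3 lower both ways of adjusting, over all genes and adjusted over the list alone (adjusted p = 0.0224; 0.388 with an estimated correlation), lost it without TWEAK replicate 2 (adjusted p = 0.148) or IL-13 replicate 3 (0.129). The test called 685 genes, 368 higher with TWEAK and 317 lower, and 74 and 43 among the 117 with no opposite exon; with total counts the balance turned, to 354 higher and 405 lower, as it did with no filter (238, 240) and without TWEAK replicate 2 (328, 337).

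TWEAK against IL-22 gave the matching comparison of single treatments. SLC12A5-AS1 (opposite MMP9) was 39.3-fold higher with TWEAK (log2 5.30 ± 0.12), and G0S2 held 31 counts against 3, a ratio of 10.8 (interval 3.36 to 55). SERPINB11 (opposite SERPINB3) was at 0.163 of its IL-22 level (-2.62 ± 0.10), SERPINB4 at 0.101, CXCL14 (opposite AC034206.1) at 0.319, MMP1 (opposite WTAPP1) at 0.414, DSG3 at 0.465, DSC3 at 0.632, KRT16 at 0.551, KRT6A at 0.645, NDRG1 at 0.547 and the ribosomal protein gene RPL23 at 0.512. Genes raised in lesional atopic dermatitis skin were lower with TWEAK, 8 of 14 with 1 higher, 11 and 1 adjusted over the list alone (adjusted p = 3.2e-09). STAT3 targets were lower in 4 of 7, 4 adjusted over the list alone (adjusted p = 1.35e-05), and STAT6 targets in 4 of 8, 5 adjusted over the list alone (adjusted p = 0.000599); with an estimated correlation these 3 lists each had an adjusted p of 0.0298. These 3 lists share members, among them SERPINB3 and SERPINB4. The lesional-skin call was kept in credited counts, with 2 of 4 lower (adjusted p = 0.00346 with an estimated correlation).

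Ribosomal protein genes, 2 of 30 lower and 4 adjusted over the list alone (adjusted p = 0.00125; 0.527 with an estimated correlation), lost the call without TWEAK replicate 2 (adjusted p = 0.163). So did hypoxia genes, 3 of 16 lower and 5 adjusted over the list alone (adjusted p = 0.0028; 0.325 with an estimated correlation; 0.0562 without that library), and wound keratins, 2 of 9 lower and 6 adjusted over the list alone (adjusted p = 0.0106; 0.379 with an estimated correlation; 0.103 without it). The ribosomal (adjusted p = 0.189) and hypoxia (0.749) calls ended in credited counts. The test called 385 genes, 249 higher with TWEAK and 136 lower, a higher share of 64.7% that became 49.2% with total counts. It called 247 without IL-22 replicate 1, 252 with no filter and 233 with DESeq2. Among the 72 called genes with no opposite exon, 25 were higher with TWEAK and 47 lower.

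**Figure D3:**
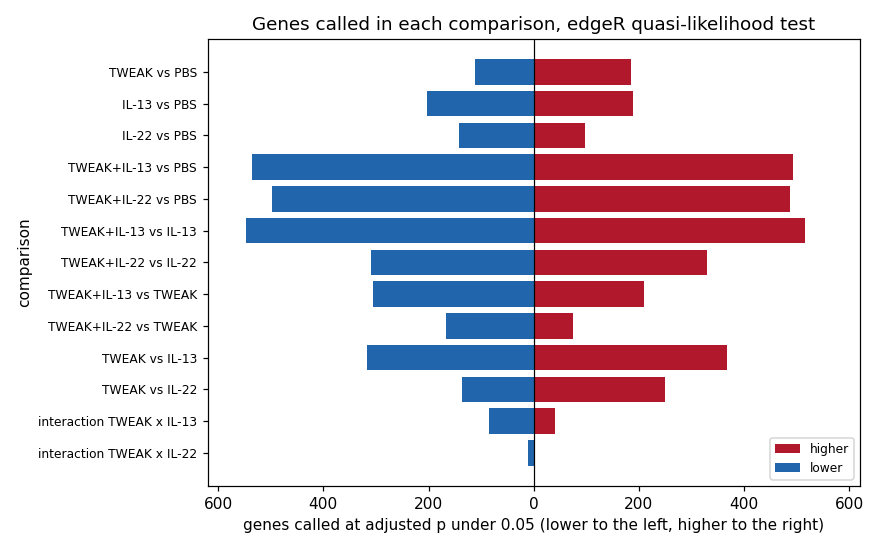
Genes called at an adjusted p under 0.05 by edgeR (x axis, number of genes; lower to the left in blue, higher to the right in red) in each comparison (y axis). TWEAK plus IL-13 against IL-13 had 515 higher and 548 lower, and the interaction of TWEAK with IL-22 had 2 higher and 11 lower.

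The interaction of TWEAK with IL-13 tested whether the pair differed from the sum of the single log2 changes. TMEM99 (opposite KRT10) lay below that sum (log2 -4.59 ± 0.41), with 136 ± 28.6 CPM with PBS, 95.4 ± 10.4 with TWEAK, 140 ± 20.9 with IL-13 and 3.49 ± 1.98 with both. DSCAS (opposite DSC1) had an interaction of -2.44 ± 0.41 and DSG1-AS1 (opposite DSG1), on chromosome 18 from 31343368 to 31426988, one of -2.24 ± 0.17, from 557 ± 57.5 CPM with IL-13 to 109 ± 20.7 with both. CRYAB (opposite HSPB2) had -2.60 ± 0.55 and HMMR-AS1 (opposite HMMR, a hyaluronan receptor gene of dividing cells) -2.13 ± 0.49. ADAMTS1, a secreted metalloprotease with no opposite exon, lay above the sum by 1.87 ± 0.26. LAMA3 lay above it by 0.98 ± 0.22, a call lost with DESeq2 (0.89) and without PBS replicate 3 (0.52).

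Matrix genes lay above the sum as a set, 2 of 17 higher and 3 adjusted over the list alone (adjusted p = 0.000447; 0.322 with an estimated correlation), as did the unfolded protein response, 1 of 11 and 1 adjusted over the list alone (adjusted p = 0.00606; 0.292 with an estimated correlation). Ribosomal protein genes, 1 of 30 higher and 4 adjusted over the list alone (adjusted p = 0.0132; 0.687 with an estimated correlation), lost the call without PBS replicate 3 (adjusted p = 0.424) or TWEAK replicate 2 (0.305). Cholesterol synthesis genes (adjusted p = 0.0335; 0.687 with an estimated correlation) lost it without PBS replicate 3 (adjusted p = 0.424), TWEAK replicate 2 (0.305), IL-13 replicate 1 (0.054) or 2 (0.1) or TWEAK plus IL-13 replicate 3 (0.0761) and with total counts (0.0541); of those 14 genes edgeR and DESeq2 called 0, and 6 higher reached an unadjusted p under 0.05. In credited counts the direction turned to below the sum for both cholesterol (adjusted p = 0.0386, and 0.27 with an estimated correlation) and ribosomal protein genes (0.485). The test called 126 genes, 41 higher and 85 lower (16 and 65 with no filter), and 172 without PBS replicate 1. Among the 19 called genes with no opposite exon, the balance was the other way, 15 higher and 4 lower. It called 58 without PBS replicate 3, 82 without IL-13 replicate 1, 80 without TWEAK plus IL-13 replicate 1, 76 with DESeq2, 81 with no filter, 69 with the CPM filter and 71 with only the groups compared.

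The interaction of TWEAK with IL-22 called 13 genes, 2 higher and 11 lower, with 351 at an unadjusted p under 0.05. In a model of only the groups compared it called 7, and 9 of 100 splits of those libraries, the real one included, gave at least that many (highest other 258). Such splits mix wells of different treatments, so effects of a single cytokine can enter them. They are no test of an interaction against chance, so they cannot decide whether this count exceeds it. In credited counts the interaction called 24 genes. DSG1-AS1 (opposite DSG1) lay below the sum (log2 -1.57 ± 0.18), as did CYP1B1-AS1 (opposite CYP1B1, -1.27 ± 0.21), H19_1 (opposite H19, -1.16 ± 0.16) and SERPINB11 (opposite SERPINB3, -0.96 ± 0.15), the last with 552 ± 35.2 CPM with TWEAK, 3380 ± 90.5 with IL-22 and 2010 ± 46.9 with both. TMEM99 (opposite KRT10) had -2.92 ± 0.61, lost without IL-22 replicate 1 (-2.38) or TWEAK plus IL-22 replicate 1 (-3.24) or 2 (-2.43). None of the 13 was free of an opposite exon. Mitochondrially encoded genes, with the high MT-RNR2 library again among the PBS wells, lay below the sum (adjusted p = 5.6e-07; 0.51 with an estimated correlation) with 0 of 13 called by edgeR or DESeq2, 2 lower adjusted over the list alone and 7 lower at an unadjusted p under 0.05. Genes raised in lesional skin also lay below it (adjusted p = 0.000593; 0.51 with an estimated correlation) with 0 of 14 called by either tool, 2 lower adjusted over the list alone and 4 lower at an unadjusted p under 0.05; the set call was lost without PBS replicate 2 (adjusted p = 0.253) or TWEAK replicate 1 (0.0567). In credited counts 2 of 4 were lower (adjusted p = 0.0109 with an estimated correlation). STAT3 targets (2 of 5 lower) and STAT6 targets (1 of 5 lower) also lay below the sum in credited counts (camera adjusted p = 0.0115 and 0.0243 with an estimated correlation). The count of 13 genes was 23 without PBS replicate 1, 22 without PBS replicate 3, 7 without PBS replicate 2 or IL-22 replicate 2, 6 without IL-22 replicate 1 or TWEAK plus IL-22 replicate 3 and 5 without TWEAK plus IL-22 replicate 1 or 2; it was 6 with no filter, 8 with the CPM filter and 7 with only the groups compared.

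Genes that the pair moved past each single treatment in the same direction were counted separately, with no condition set against PBS. TWEAK plus IL-13 moved 270 genes in this way, 116 higher and 154 lower, and 54 of them also passed the interaction test in that direction. TWEAK plus IL-22 moved 127 genes, 39 higher and 88 lower, and 8 of them passed the interaction test. The count of 270 was 177 with DESeq2, 173 with no filter and 179 with the CPM filter. The count of 127 was 54 with no filter, 64 with the CPM filter, 83 without TWEAK plus IL-22 replicate 2 and 84 without TWEAK plus IL-22 replicate 3.

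Across the 6179 genes, changes against the shared PBS wells correlated between TWEAK and IL-13 with r = 0.496, between TWEAK and IL-22 with 0.563 and between IL-13 and IL-22 with 0.593 (Spearman's rho 0.488, 0.539 and 0.513). In simulations, PBS and both treated groups were redrawn at their depths from a common rate per gene, which gave r of 0.645, 0.645 and 0.649. These draws lack the make-up of PBS replicate 1 itself, so differences from them cannot show a shared response. The covariances were 0.146, 0.142 and 0.156, against 0.0906, 0.089 and 0.0906 simulated, differences of 0.0555, 0.0529 and 0.0651. The same sign was seen in 67.6, 70.1 and 67.6% of genes, against 71.6, 71.7 and 71.7% simulated. TWEAK and IL-13 shared 34 higher and 40 lower calls, where independent lists would share 5.63 and 3.65, TWEAK and IL-22 36 and 49 (2.9 and 2.57), and IL-13 and IL-22 43 and 72 (2.95 and 4.7). Called genes went in opposite directions in 17, 3 and 3 cases. Genes are not independent replicates, and part of the excess may come from the shared wells, which are too few to split.

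Several lists were called in no comparison of the counts as deposited; antigen presentation, terminal differentiation, cell cycle and immediate early genes were called in some when counts were credited to the gene on the other strand, as given under other observations. The lowest adjusted p over the comparisons was 0.0529 for the 9 measured terminal differentiation genes, 0.0588 for the 8 immediate early genes, 0.0986 for the 15 tight junction and adhesion genes, 0.148 for the 10 antigen presentation genes, 0.268 for the 9 cytokines and growth factors, 0.397 for the 9 cell cycle genes and for the 4 genes lowered in lesional atopic dermatitis skin, 0.407 for the 6 barrier lipid genes and 0.412 for the 9 TNF receptor and death signalling genes. With an estimated correlation, the list calls that held were STAT6 targets after IL-13, STAT6 targets when IL-13 was added to TWEAK, STAT6 targets and interferon-stimulated genes between TWEAK and IL-13, and genes raised in lesional skin, STAT3 targets and STAT6 targets between TWEAK and IL-22. Every list call that fry ended was also lost with an estimated correlation. Antimicrobial peptides had 2 tested genes, CXC chemokines 2 and CC chemokines 0, too few for a set test. Many genes of interest held almost no counts over the 18 libraries: CCL2, DEFB4A and S100A7 held 0, CCL26 and CCL5 1 each, CCL17, CCL20, CXCL10 and LOR 2 each, TSLP 6, CXCL8 10, KRT1 48 and IVL 49. Changes in these genes were not tested. Low counts of a gene do not show low expression here, because GAPDH itself held 787 counts against 481397 for AC006064.4 opposite it. The same limit holds for FLG, KRT10 and the marker genes that follow. FLG, the filaggrin gene, held 1136 counts, and KRT10 itself 376. Marker genes of other cell types held 38 counts for fibroblasts, 26 for endothelium, 45 for sweat gland and other simple epithelium, 218 for leukocytes and Langerhans cells, and 3358 for melanocytes, the last including PMEL, whose exons overlap CDK2 on the other strand. PMEL (opposite CDK2) rose by 0.59 ± 0.14 with IL-13.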

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

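Of the tests below, those of strand and those of MT-RNR2 in PBS replicate 1 were chosen only after the result was seen; the others had predictions written before.

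Most counts lay in genes opposite abundant messengers. If counting used the strand opposite to that of the library, MT-ND6 should exceed the heavy-strand messengers per kb, and it did by 29.7-fold. A kit that does not mark strand would give protein-coding genes without an opposite exon a share of protein-coding counts near their 60% of exon length; they held 17.1%, which excludes it. Antisense transcription in the cells would leave the ribosomal protein messengers in place, and these held 0.198% of counts, which excludes it too, so a stranded library counted with the opposite setting likely explains the pattern. Changes of a gene and its opposite partner also correlated across 1434 pairs, with r from 0.0949 to 0.497 over the comparisons against at most 0.0823 in shuffled pairs of the lowest comparison, so both may draw on the same transcripts.

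PBS replicate 1 stood apart from the other PBS wells. On log2 CPM of tested genes with a prior scaled to each pair, its correlation with replicates 2 and 3 was 0.804 and 0.773. Those replicates thinned to its 39724 counts gave 0.832 to 0.845 (mean 0.838), above both values in every draw. The thinned values still lie under the bound of 0.85 set before for excluding low depth alone, so by that bound the test could not tell. The MT-RNR2 share of replicate 1 has an exact lower bound of 0.248% against at most 0.0478% elsewhere, which depth does not explain. The share was 6.27 times the highest of the others, as RNA of another make-up or quality might give. A treated well with the wrong label was excluded, since SLC12A5-AS1, SERPINB11 and TMEM99 lay within 1.46-fold of the other PBS wells, on 11, 16 and 5 counts. No biological explanation was tested for it.

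Genes opposite KRT10, DSC1 and DSG1 fell further with TWEAK plus IL-13 than the single treatments add up to. A single library was excluded as the cause, since the weakest of the 3 interactions without any 1 library was -1.92, and so was scaling, with -2.19 as the weakest under RLE factors or total counts. A joint action of both cytokines on these loci was not tested in any other way and stays open.

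Effects of TWEAK that differed between cells with and without IL-13 were picked out by the interaction test and are log2 values. Those that kept the call in every alternative fixed in advance were ADAMTS1 1.87, TMEM99 -4.59, CRYAB -2.60, DSCAS -2.44, DSG1-AS1 -2.24 and HMMR-AS1 -2.13. Those that lost it in at least 1 were LAMA3 0.982, PKM 0.933, API5 2.49, FRYL 1.83, CYR61 1.70, ELK3 1.70, ZNF706 -1.95, RPL11 0.724, DSG1 -1.93 and HSP90B1 0.84. For IL-22, DSG1-AS1 -1.57, CYP1B1-AS1 -1.27, H19_1 -1.16 and SERPINB11 -0.96 kept the call, and ARRDC1 1.56, TMEM99 -2.92 and PRICKLE2-AS1 -0.757 lost it in at least 1.

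Random splits of the libraries showed how many genes other groupings give, in models of only the groups compared. For contrasts of 3 against 3, the 10 splits are too few for a share under 0.05, and in each the real split alone, 1 of 10, had as many genes. The real and highest other counts were 147 and 0 for TWEAK against PBS, 270 and 1 for IL-13, 155 and 2 for IL-22, 816 and 0 for TWEAK plus IL-13 and 780 and 0 for TWEAK plus IL-22. They were 1269 and 0 for TWEAK plus IL-13 against IL-13, 949 and 0 for TWEAK plus IL-22 against IL-22, 560 and 0 for TWEAK plus IL-13 against TWEAK and 315 and 0 for TWEAK plus IL-22 against TWEAK. TWEAK against IL-13 gave 696 and 0, and against IL-22 419 and 0. For the interaction with IL-13, 2 of 100 splits had as many as the real 71 (highest other 108). For genes moved past both single treatments it was 1 of 100 for TWEAK plus IL-13 (309, highest other 218) and 2 of 100 for TWEAK plus IL-22 (178, highest other 192). The interaction with IL-22 was matched in 9 of 100 splits (7 real, highest other 258). Splits for the interactions and for genes moved past both single treatments mix wells of different treatments. Effects of single treatments can therefore enter the split counts, which cannot decide whether any of these real counts exceeds chance.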

How the results depend on the processing

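Of 428 named gene results, 238 kept their call in every alternative fixed in advance and 190 lost it in 1 or more. None reversed in these alternatives. Crediting counts to the gene on the other strand was not among them, so these numbers do not cover the strand of the counts. Over 429 gene results, including TNFRSF12A, 4912 values kept their side of the threshold and 764 were weaker: 89 with DESeq2, 75 with no filter, 70 with the CPM filter, 29 with only the groups compared, 16 with total counts, 10 with RLE factors, 8 with the block, and between 2 (without PBS replicate 1) and 53 (without PBS replicate 2) with 1 library left out. DESeq2 gave no adjusted p for some low-count genes, which then have no value. Causes were not tested, except that unfiltered tables test more genes and left-out libraries leave fewer samples.

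Counts of called genes with no filter were 197 for TWEAK against PBS, 124 for IL-22 against PBS, 387 for TWEAK plus IL-22 against IL-22, 119 for TWEAK plus IL-22 against TWEAK, 252 for TWEAK against IL-22, 81 and 6 for the interactions with IL-13 and IL-22, and 173 and 54 beyond both singles. With the CPM filter they were 193, 133, 405 and 129 for the first 4 of these, 69 and 8 for the interactions, and 179 and 64 beyond both singles. DESeq2 gave 679 for TWEAK plus IL-13 against IL-13, 401 for TWEAK plus IL-22 against IL-22, 337 for TWEAK plus IL-13 against TWEAK, 233 for TWEAK against IL-22, 76 for the interaction with IL-13 and 177 beyond both singles of TWEAK plus IL-13. Only the groups compared gave 147 for TWEAK against PBS, 155 for IL-22 against PBS, 71 and 7 for the interactions. Counts credited to the other strand, chosen after the data were seen, gave 24 for the interaction with IL-22.

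Leaving out 1 library gave 199 to 367 genes for TWEAK against PBS, 259 to 472 for IL-13, 120 to 308 for IL-22, 158 to 234 for TWEAK plus IL-22 against TWEAK, 247 to 347 for TWEAK against IL-22, 58 to 172 and 5 to 23 for the interactions and 83 to 118 beyond both singles of TWEAK plus IL-22. Lists called then ranged from 1 to 4 for TWEAK, 3 to 10 for IL-22, 3 to 7 for TWEAK plus IL-13 and 1 to 3 for TWEAK plus IL-22 against PBS, 2 to 7 and 1 to 3 for the pairs against IL-13 and IL-22, 3 to 6 and 1 to 6 for the pairs against TWEAK, 3 to 9 for TWEAK against IL-22 and 1 to 6 for the interaction with IL-22.

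With an estimated correlation, lists called were 1 for IL-13 against PBS, 1 for TWEAK plus IL-13 against TWEAK, 2 for TWEAK against IL-13, 3 for TWEAK against IL-22 and 0 elsewhere. With fry they were 0 for TWEAK, 3 for IL-13, 3 for IL-22 and 6 for TWEAK plus IL-13 against PBS, 8 for TWEAK plus IL-13 against IL-13, 3 for TWEAK against IL-22 and 0 for both interactions. Total counts gave 3 for TWEAK plus IL-13 against IL-13 and 1 for TWEAK plus IL-22 against IL-22. Correlations between changes against PBS (TWEAK and IL-13, TWEAK and IL-22, IL-13 and IL-22) were 0.611, 0.647 and 0.643 with the CPM filter, 0.474, 0.586 and 0.7 over called genes, and 0.499 to 0.727, 0.56 to 0.795 and 0.598 to 0.797 with 1 library left out.

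Replicate numbers did not pair the wells: mean r was 0.00647 over 45 pairs of libraries of the same number, 2 of them above 0.1, and 11 libraries were closer to their own number. A block per number gave 304 genes for TWEAK, 405 for IL-13 and 236 for IL-22 against PBS, 137 and 17 for the interactions, and 6 lists for TWEAK plus IL-22 against TWEAK; other counts also stayed within 1.5-fold. At this depth and with 3 wells per group, for TWEAK against PBS the simulated test found 29.9% of 1.5-fold changes.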

Other observations

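Crediting each count to the overlapping gene on the other strand, a choice made only after the data were seen, turned the pairs above into gene names and is given as values. It tested 4203 genes, and TWEAK against PBS then called 317, 170 higher and 147 lower, by edgeR. Antigen presentation genes rose in 5 of 6 after TWEAK (adjusted p = 0.00429 with an estimated correlation): the class I heavy chain genes HLA-B (log2 0.98 ± 0.09) and HLA-F (1.31 ± 0.14), the immunoproteasome gene PSMB8 (0.98 ± 0.10) and the peptide-trimming gene ERAP1 (0.62 ± 0.12). NF-kB genes rose in 2 of 7 (adjusted p = 0.0205 with an estimated correlation), with MAP3K14, the kinase of the non-canonical pathway, by 1.08 ± 0.16, and IRF1 rose by 1.92 ± 0.31. Interferon-stimulated genes rose in 3 of 5, with XAF1 by 1.90 ± 0.18 and MX1 by 0.60 ± 0.08, and matrix genes counted 5 risen and 1 fallen of 8, with MMP9 up by 5.05 ± 0.13 (each adjusted p = 0.0205 with an estimated correlation). Antigen presentation genes were also higher when TWEAK was added to IL-13 (5 of 6 risen, 1 fallen; adjusted p = 0.00449 with an estimated correlation) or to IL-22 (5 of 6; 0.00555), in both pairs against PBS (0.00659 and 0.00639), and with TWEAK against IL-13 (0.0175) and IL-22 (0.00192). Of 5 in the unfolded protein response, 2 rose after TWEAK (adjusted p = 0.0336 with an estimated correlation).

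In the same credited counts, 4 of 4 terminal differentiation genes fell after IL-22 (adjusted p = 5.24e-05 with an estimated correlation): KRT10 by 2.83 on the log2 scale, DSC1 by 2.17, CDSN by 0.93 and DSG1 by 0.56. The list was mixed after IL-13, with 1 risen and 2 fallen of 4 (camera adjusted p = 0.0389, direction lower, and 0.121 with an estimated correlation). KRT10 changed by -5.34 ± 0.33 with TWEAK plus IL-13 and -6.41 ± 0.37 with TWEAK plus IL-22, with 4 of 4 fallen in both pairs against PBS (adjusted p = 0.000496 and 0.000672 with an estimated correlation) and against TWEAK (6.43e-05 and 1.97e-05). When TWEAK was added to IL-13 or IL-22, 3 of 4 fell (adjusted p = 0.00351 and 0.0138 with an estimated correlation), TWEAK was above IL-22 in 4 of 4 (0.000373), and the list lay below the sum of the single treatments in both interactions (adjusted p = 0.000153 and 0.00136 with an estimated correlation). After IL-13, STAT6 targets rose in 2 of 5, with CISH, a feedback inhibitor of cytokine signalling, by 2.82 ± 0.25 and SERPINB3 by 3.96 ± 0.11, and cell cycle genes rose in 3 of 6, with FOXM1 by 0.61 ± 0.10 (each adjusted p = 0.0123 with an estimated correlation). In the interaction of TWEAK with IL-13, FOXM1 changed by -0.58 ± 0.14 and cell cycle genes lay below the sum (adjusted p = 0.00585 with an estimated correlation); they were also lower when TWEAK was added to IL-13 (3 of 6; adjusted p = 0.0253) and with TWEAK against IL-13 (2 of 6; adjusted p = 0.025).

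In credited counts, immediate early genes were lower by the preset camera test after IL-22 (2 of 5; adjusted p = 0.0107, 0.185 with an estimated correlation), after TWEAK plus IL-22 (3 of 5; adjusted p = 0.0394, 0.211), when TWEAK was added to IL-13 (3 of 5; adjusted p = 0.0318, 0.192) and when IL-22 was added to TWEAK (3 of 5; adjusted p = 0.00272, 0.11). They were higher with TWEAK against IL-22 (2 of 5; adjusted p = 0.0485, 0.242) and lay below the sum in the interaction with IL-13 (adjusted p = 0.0245, 0.196), and none of these calls held with an estimated correlation.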
